A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

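Gene expression was measured in 48 samples of budding yeast on Affymetrix Yeast Genome 2.0 arrays, which also carry fission yeast probe sets. Small daughter cells were taken by elutriation from cultures kept at 25 °C and put into rich medium (YEPD) at 37 °C at 0 min. Samples were grouped by strain and time as the labels give them, and the replicate number is the course: 2 courses of cdc28-4 (33 arrays) and 1 course of wild type (15 arrays). Per the labels, RNA of samples 1 to 33 was labelled with a One Cycle kit and that of samples 34 to 48 with a MessageAmp Premier kit. Read in listing order, these are all the cdc28-4 and all the wild-type samples, and the labels give no other key to those numbers.

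The authors processed the array images with the R package affy, whose version and whose summary and normalization methods are not given in the sources used here. The deposited values are linear intensities, 1 per probe set and array, for 10928 probe sets. No value was under 1, and log2 was taken without an added constant. Of the probe sets, 5498 had 1 S. cerevisiae gene in the annotation, 1 had several, 1746 had genes of another organism, 166 were controls and 3517 had no gene. For the 47 genes with more than 1 probe set, the one with the highest mean was kept, leaving 5449 genes, and 12 symbols were updated through the gene identifier. List members with no usable probe set, such as HHF2, HXT6 and PHO12, were left out. Background is the 95th percentile of the fission yeast probe sets, at a mean level of 8.27 on the log2 scale (intensity 308), and from 270 to 462 on single arrays. A fold against a group under background is given as a lower bound, computed against that level. Arrays hold no counts, so no counting depth applies, and the number of arrays limits the precision.

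All tests used R 4.3.3 and limma 3.58.1, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05, and were two-sided. One fit of 48 arrays had a mean for each of the 33 combinations of strain and time, 15 residual degrees of freedom (all from the cdc28-4 pairs) and 4.00 prior degrees of freedom. It gave the time effect in cdc28-4 over 15 shared times (F test), the contrast of 10 with 90 min, and that of 270 and 290 with 90 and 110 min. It also gave the interaction of strain and time at the 4 times both strains share (30, 90, 150 and 210 min), with the change from 30 to 90 min as 1 contrast. Single wild-type arrays enter this fit on the assumption that they vary like the cdc28-4 pairs. Levels of the strains were compared as means over the 4 matched times, 1 per course, in a fit of 3 course means, whose spread comes from the 2 cdc28-4 courses alone and was assumed for wild type.

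Periodicity was tested in each strain with a limma F test of a cosine and a sine over an intercept, a linear and a quadratic trend of each course. One period was shared by all genes, the value on a grid from 50 to 160 min in steps of 2 with the highest mean share of detrended variance over 125 genes of the cell cycle lists, chiefly SBF, MBF, histone, Hcm1, CLB2 and Mcm1 genes. The period was chosen on the same arrays as the test, which favours the fit of those 125 genes. Amplitudes were compared between strains among the genes periodic in wild type, each strain at its own period, which favours a larger value in wild type. Peak order was to be compared by a circular correlation of phases over genes periodic in both strains, with permutation of genes. The profiles of both cdc28-4 courses were compared by Pearson's r per gene over 15 times after a quadratic trend was removed, with 10000 random lists of like expression for each list.

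The 23 gene lists were written from general knowledge of yeast before the data were examined: cyclins and Cdk regulators (17 genes measured), cell cycle transcription factors (17), SBF targets (19), MBF targets and DNA replication (31), histones (8), S-phase Hcm1 targets and spindle (19), and the CLB2 cluster (19). Further lists were Mcm1 M/G1 genes (10), pheromone-induced genes (16), a-specific (6) and alpha-specific genes (4), and meiosis and sporulation (18). The rest were heat shock chaperones (26), Msn2/4 stress genes (23), cell wall integrity (11), ribosome biogenesis (32), ribosomal proteins (18), glucose-repressed genes (21), hexose transporters (5), phosphate (14), methionine and sulfate (18) and iron (15). Some genes are in more than 1 list, and 1 of the 23 is not reported here. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists, and periodic genes were counted per list with Fisher's exact test.

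The genes named were chosen by a rule set before the data were examined: all cyclins, Cdk regulators and cell cycle transcription factors in the tests of periodicity and amplitude, and the 5 largest rises and 5 largest falls past the threshold and above background in each contrast. It added the 5 highest F of each F test, up to 3 members of each list with the largest change, and BAR1 and CDC28. Named after their values were seen were further cyclins, transcription factors and alpha-specific genes in the contrasts, the genes of highest F after 30 min, and the genes of the peak order.

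Whether the replicate numbers pair the cdc28-4 arrays was checked by the correlation over genes of the difference between courses at 1 time with that at another. Over 105 pairs of times it ran from 0.005 to 0.898 (median 0.468), and 97 exceeded 0.1, so a fit with the course as a block was run as an alternative (replicate block). The contrasts were tested on simulated data of 5449 genes, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. The shares found were 83.6%, 98.5% and 100% for 10 against 90 min, 68.7%, 97.0% and 100% for the time effect and 95.5%, 100% and 100% for the late contrast. They were 47.8%, 85.1% and 100% for the interaction, 43.3%, 88.1% and 100% for the change from 30 to 90 min and 94.0%, 100% and 100% for the level. They were 100% at every size for periodicity in either strain and for the amplitude. From 5 to 12 of 5249 unchanged genes were called, and simulated periods of 80 and 100 min were found as such. The simulated genes were flat apart from the change, with independent noise of the size between cdc28-4 pairs and no response to the shift. For the amplitude, 1 period was fitted in both strains. These shares are therefore not the power in the real courses. In the real wild-type course the gene TOS6, at an amplitude of 0.678, did not pass over all times (limma F test, adjusted p = 0.0974).

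Alternatives fixed beforehand were centring each array on its median, quantile normalization, a filter on genes under background, every probe set kept, and leaving out each array, course or matched time. So were a spline with 6 degrees of freedom, other trends, periods, harmonics and windows, a period per gene against 100 shuffles of the times, and a shift of 1 course by 20 min. Chosen after seeing the data were the change from 30 to 90 min as a contrast, centring on the fission yeast probe sets, and the wild-type period in cdc28-4. Further ones were leaving out the 170 min array of course 2 or both 170 min arrays, leaving out courses in the interaction, and the scalings, omissions and peak order for samples after 30 min. The 3 later cdc28-4 times of course 2 (310 to 350 min) have no second course and entered the fits of periodicity and the plots.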

Results

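Messenger RNA of budding yeast was measured on 48 single-colour Affymetrix expression arrays, 1 array per sample, in 3 time courses. Each culture began as small daughter cells, which are early in their first cell cycle, separated by size in an elutriation rotor from cultures kept at 25 °C. Time 0 min is the moment the cells were put into rich medium at 37 °C. The cdc28-4 strain carries a temperature-sensitive form of CDC28, the gene of Cdk1, the kinase that drives the cell cycle, and its samples are labelled as having no Cdk activity at 37 °C. It has 2 courses, sampled every 20 min, with 15 arrays from 10 to 290 min in course 1 and 18 arrays from 10 to 350 min in course 2. The wild-type strain, which has normal CDC28 and the bar1 genotype (BAR1 encodes the protease that destroys alpha-factor), has 1 course of 15 arrays from 15 to 225 min, sampled every 15 min. Thus 15 times hold 2 cdc28-4 arrays each, and the other 18 combinations of strain and time hold 1 array and have no replicate. After removal of probe sets for fission yeast and controls, 5449 genes were measured. The median intensity of an array lay between 394 and 473, and from 90.8% to 96.6% of the genes on an array lay above the level of fission yeast probe sets, which have no target in these cells. The number of arrays limits the precision of every value below. Values are log2 intensities and differences are log2 differences. SE is the standard error from limma, and a gene is said to differ, rise or fall when its adjusted p was under 0.05.

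The first comparison, 10 min against 90 min in cdc28-4 (2 arrays each), shows the cells soon after the move to 37 °C. Genes driven by Msn2 and Msn4, the transcription factors of the general stress response, stood high: 22 of 23 were higher at 10 min, with a median difference of 1.68. Among them were CTT1 (YGR088W), the cytosolic catalase, at 3.75 (SE 0.16), the transketolase gene TKL2 at 3.65 (SE 0.20) and the aldehyde dehydrogenase gene ALD3 at 3.28 (SE 0.21). Ribosome biogenesis genes, whose products assemble new ribosomes in growing cells, stood low: all 32 were lower at 10 min, with a median of -1.89 and with the nucleolar gene NSR1 (YGR159C) at -3.23 (SE 0.11). Targets of SBF, the Swi4-Swi6 factor that switches on G1 genes, were also low at first, 16 of 19 with a median of -1.33. The G1 cyclin gene CLN2 (YPL256C), an SBF target, stood at 9.0 at 10 min and 10.77 at 90 min, a difference of -1.77 (SE 0.11).

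Heat shock chaperone genes were split, with 15 of 26 higher at 10 min and 2 lower (median 0.43), led by HSP30, a membrane protein gene, at 3.90 (SE 0.24) and HSP42, a small heat shock protein gene, at 1.90 (SE 0.10). Glucose-repressed genes, which serve growth on other carbon sources, were higher in 16 of 21 and lower in 2 (median 0.85), and the invertase gene SUC2 was higher by 3.70 (SE 0.11). Mcm1 genes of the M/G1 boundary, which prepare the next round of replication, were lower at 10 min in 9 of 10 (median -0.53). Cyclins and Cdk regulators were lower in 11 of 17 and higher in 3 (median -0.52). Histone genes were higher in 6 of 8 (median 0.42), with the linker histone gene HHO1 at 1.38 (SE 0.064). These 8 lists passed the camera list test with its preset correlation, with adjusted p from 1.94e-14 for ribosome biogenesis to 0.0306 for the cyclins. With an estimated correlation between the genes of a list none passed: adjusted p = 0.212 for the Msn2 and Msn4, ribosome biogenesis, SBF, glucose-repressed, Mcm1 and cyclin lists, 0.485 for the chaperones and 0.684 for the histones. Counts adjusted over the list alone were the same for these 8 lists, and with quantile normalization the histone list did not pass (median 0.35), with adjusted p of 0.0217 and 0.0682 over 2 scalings. MBF targets, the S-phase genes of the Mbp1-Swi6 factor, were lower in 17 of 31 and higher in 3 without passing as a list (median -0.29, adjusted p = 0.0705). Phosphate genes, which take up and store phosphate, were lower in 9 of 14 (median -0.54, adjusted p = 0.0665). Ribosomal protein genes were lower in 7 of 18, both over all genes and adjusted over the list alone, also without a list call (median -0.12, adjusted p = 0.589).

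Among single genes, YNL194C, which encodes a membrane protein of the cell cortex, was 24.1-fold higher at 10 min than at 90 min (log2 4.59 (SE 0.11), adjusted p = 1.58e-16). It was followed by the dehydrogenase gene BDH2 at 4.52 (SE 0.24) and the reticulon gene RTN2 at 4.15 (SE 0.17). The kinase gene RCK1, which was under background at 90 min, was at least 8.94-fold higher at 10 min. The phosphate transporter gene PHO84 was the furthest below its 90 min level, at -3.71 (SE 0.21), followed by NSR1 and by the ribosome assembly genes ARX1 at -3.16 (SE 0.10), RPF2 at -3.16 (SE 0.079) and PUF6 at -3.12 (SE 0.099). In all, 3798 of 5449 genes (69.7%) differed between 10 and 90 min by limma, 1617 higher at 10 min and 2181 lower. With each array centred on its median the split was 1836 and 1794. In the wild-type course, which has 1 array at each time and no test of its own here, the median difference between 15 and 90 min was 1.93 for the Msn2 and Msn4 genes, -2.14 for ribosome biogenesis, and -1.72 for SBF targets. It was 1.15 for the chaperones and -0.53 for the histone genes, whose sign is opposite to that in cdc28-4.

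**Figure D1:**
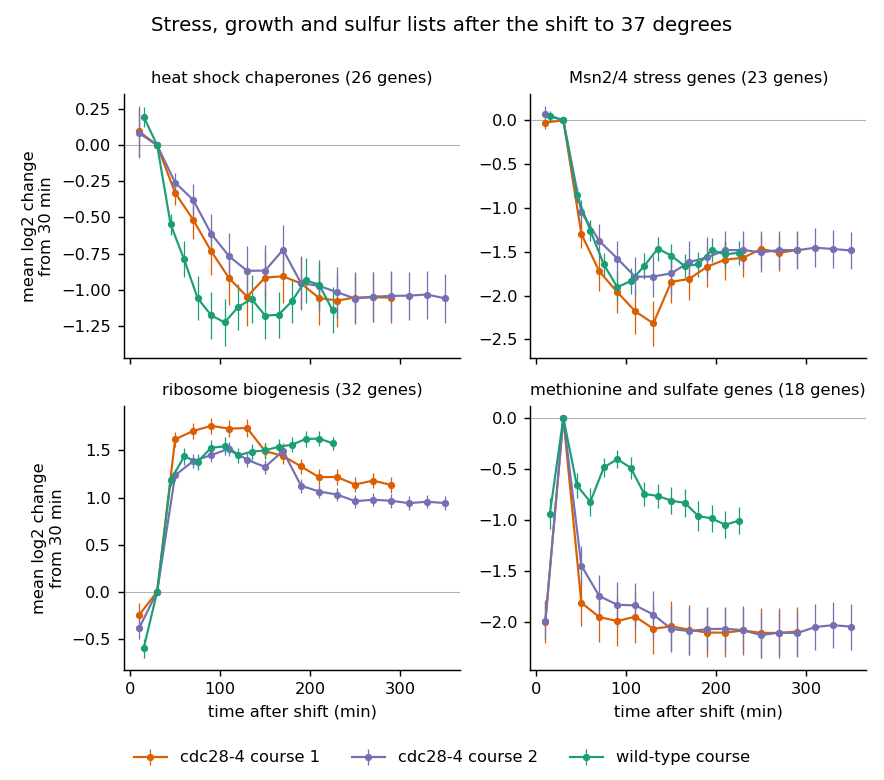
Mean log2 intensity change from 30 min (vertical axis) against minutes at 37 °C (horizontal axis) for heat shock chaperones, Msn2/4 stress genes, ribosome biogenesis and methionine and sulfate genes, 1 line per course, with bars for the standard error over the genes of a list. The methionine and sulfate genes sank to -2.11 and -2.13 in the cdc28-4 courses and to -1.05 in wild type.

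The second comparison, 270 and 290 min against 90 and 110 min in cdc28-4 (4 arrays each), asked how expression went on in cells labelled as lacking Cdk activity. G1 and S-phase cyclin genes went on rising: the Pho85 cyclin gene PCL1 (YNL289W) rose by 2.04 (SE 0.056), CLN2 rose from 10.85 to 12.55 and CLN1 by 1.49 (SE 0.081). The S-phase cyclin genes CLB6 and CLB5 rose by 1.62 (SE 0.059) and 0.49 (SE 0.054). The mitotic cyclin gene CLB1 (YGR108W) rose by 1.90 (SE 0.081), and its sister CLB2 had a smaller difference (0.19 (SE 0.092)). The call for CLB2 depended on the fit: it did not pass here (adjusted p = 0.0810) and passed with the replicate block, which pairs the arrays by course (adjusted p = 0.00360). It passed in 4 of its 16 alternatives, with adjusted p from 0.00360 to 0.293. SBF targets rose in 17 of 19 and fell in 1, with a median of 0.98. Cyclins and Cdk regulators rose in 12 of 17 and fell in 2, with a median of 0.49. Genes of the cell wall integrity pathway, which the kinase Slt2 switches on when the wall is strained, rose in 10 of 11 (median 0.70). Among them was YPS3 (YLR121C), a gene for a protease of the cell surface, with the largest rise of all named genes at 2.94 (SE 0.11).

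Further cell cycle groups rose by less. MBF targets rose in 23 of 31 (median 0.24), with the cohesin gene MCD1 at 1.08 (SE 0.079) and RNR1, which encodes ribonucleotide reductase, at 1.02 (SE 0.047). Histone genes rose in 7 of 8 (median 0.37), and genes of the CLB2 cluster, which peak in mitosis, in 12 of 19 (median 0.21). So did genes for cell cycle transcription factors, in 9 of 17 (median 0.28), with the repressor genes YOX1 at 1.30 (SE 0.13), ASH1 at 1.24 (SE 0.097) and YHP1 at 1.06 (SE 0.047). Stress and carbon genes also rose, 16 of 23 Msn2 and Msn4 genes (median 0.50) and 10 of 21 glucose-repressed genes (median 0.20). Ribosome biogenesis genes fell in 31 of 32 (median -0.54). Chaperone genes fell in 20 of 26 (median -0.29), with SSA4, an inducible Hsp70 gene, at -0.77 (SE 0.092), and phosphate genes in 8 of 14 (median -0.26). Adjusted over the list alone, the counts differed only for MBF targets, with 24 rising, and for the chaperones, with 21 falling.

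All of these late lists passed camera with the preset correlation, with adjusted p from 5.38e-12 for SBF targets to 0.0215 for the glucose-repressed genes. With an estimated correlation the SBF targets (adjusted p = 0.0302) and the cyclins (adjusted p = 0.00646) still passed. The others were lost, with adjusted p = 0.108 for the cell wall genes, 0.187 for the MBF targets, 0.201 for ribosome biogenesis, 0.212 for the chaperones and 0.242 for the histones. It was 0.250 for the CLB2 cluster and the transcription factors, 0.327 for glucose-repressed, 0.394 for phosphate and 0.422 for the stress genes. The spindle and Hcm1 genes rose in 8 of 19 (7 adjusted over the list alone) without a list call (median 0.12, adjusted p = 0.122). Meiosis and sporulation genes rose in 7 of 18 (6 adjusted over the list alone; median 0.11, adjusted p = 0.0879), whereas the Mcm1 genes rose in 1 and fell in 4 of 10 (adjusted p = 0.731). Iron regulon genes rose in 2 (1 adjusted over the list alone) and fell in 3 of 15 (adjusted p = 0.764). Hexose transporter genes rose in 2 and fell in 2 of 5, and the median of -0.20 and the upward direction of the test differed in sign (adjusted p = 0.852).

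In all, 3065 genes (56.2%) differed between the early and the late window, 1480 rising and 1585 falling. This balance turned with the scaling: 1175 rose and 1803 fell with each array centred on its median, and 1649 rose and 1242 fell with arrays centred on the fission yeast probe sets, a scaling chosen after seeing the data. The ratio of 3′ to 5′ control probe sets, a sign of RNA quality, also rose in this contrast, on the log2 scale from 0.96 and 0.92 to 1.13 and 1.09 in course 1 and from 0.78 and 0.75 to 0.95 and 1.03 in course 2. The largest rises after YPS3 were those of RIM4, a regulator gene of meiosis, at 2.19 (SE 0.096), the maltase gene MAL32 at 2.17 (SE 0.12). Next came the proline permease gene PUT4 at 2.09 (SE 0.12) and YBR071W, a gene of unknown function, at 2.09 (SE 0.093). The adenine deaminase gene AAH1 fell by 1.77 (SE 0.072), YDR222W by 1.49 (SE 0.061) and the copper transporter gene CTR1 by 1.32 (SE 0.085). DED1, which encodes an RNA helicase of translation, fell by 1.37 (SE 0.42) with all arrays (adjusted p = 0.00913). It did not pass without the course 1 array at 270 min (-1.02, adjusted p = 0.0640) or at 290 min (-1.12, adjusted p = 0.0525), nor between 290 and 90 min alone (-1.42, adjusted p = 0.0604). Over its 16 alternatives the adjusted p ran from 3.6e-06 to 0.0640.

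Genes of the mating type moved in the same window. The cells are MATa, so the alpha-factor and alpha-cell genes are normally silent. Late in cdc28-4 3 of 4 alpha-specific genes rose (median 0.72; adjusted p = 0.00953, and 0.0929 with an estimated correlation). These were MF(ALPHA)1 (YPL187W), the main alpha-factor gene, by 1.07 (SE 0.076), the agglutinin gene SAG1 by 1.00 (SE 0.13) and STE3, the receptor gene for a-factor, by 0.43 (SE 0.062). The other member, MF(ALPHA)2, did not pass (0.20 (SE 0.11), adjusted p = 0.142). SAG1 had signal above background before its rise, with a lowest mean of 9.86 at 50 min in cdc28-4. Over the matched times MF(ALPHA)1 went from 7.50 at 30 min to 8.52, 10.65 and 10.999 at 90, 150 and 210 min in cdc28-4. In wild type it stayed between 7.13 and 7.35, under the background level of 8.27. The a-specific genes, which these cells use for mating, fell in 4 of 6 (median -0.45; adjusted p = 0.0424, and 0.318 with an estimated correlation). Among them were BAR1 at -0.91 (SE 0.11) and the a-factor genes MFA2 at -0.66 (SE 0.065) and MFA1 at -0.61 (SE 0.047). This list did not pass with quantile normalization (median -0.45), with adjusted p from 0.0302 to 0.0524 over 3 scalings. Pheromone-induced genes fell in 8 of 16 and rose in 1 without a list call (median -0.18, adjusted p = 0.0673), and passed with arrays centred on the fission yeast probe sets (median -0.14). FUS3, the kinase gene of the mating pathway, fell by 0.82 (SE 0.043). Counts adjusted over the list alone were the same for these 3 lists.

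**Figure D2:**
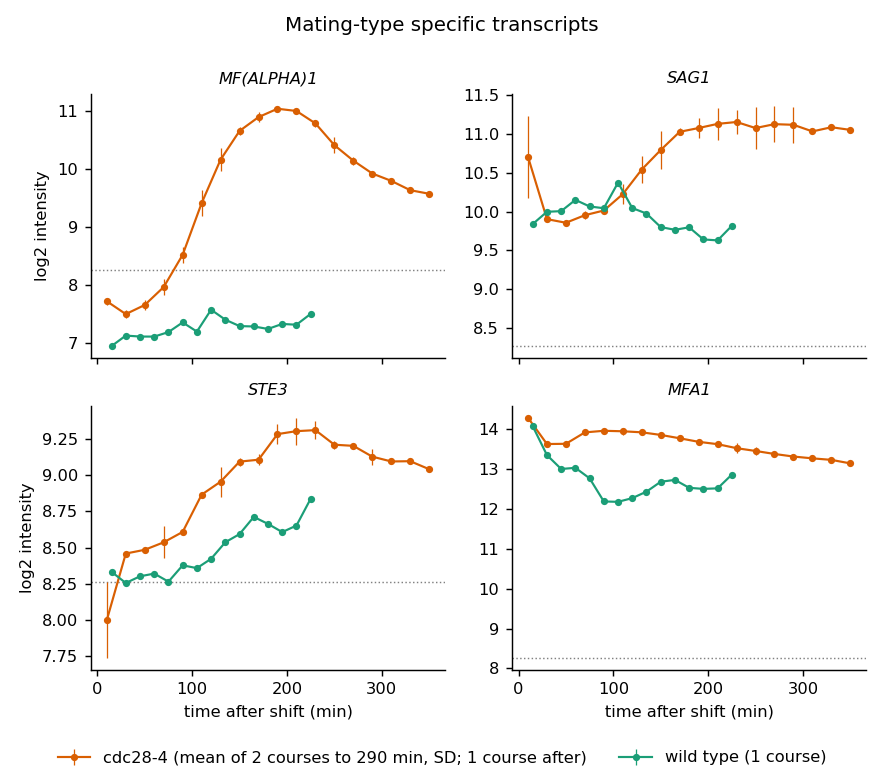
Log2 intensity (vertical axis) of MF(ALPHA)1, SAG1, STE3 and MFA1 against minutes at 37 °C (horizontal axis). The cdc28-4 line is the mean of 2 courses with their standard deviation up to 290 min and 1 course after that, and the wild-type line is 1 course. The dotted line is the background of 8.27, above which MF(ALPHA)1 climbs in cdc28-4 alone, with its highest mean at 190 min and a fall after that.

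Over the whole course of cdc28-4, most transcripts changed with time. All 32 ribosome biogenesis genes, all 26 chaperone genes, all 18 methionine and sulfate genes and 18 of 19 SBF targets did, with the same counts adjusted over the list alone. Among the highest F was CSI2, a chitin synthesis gene, which went from 8.79 at 10 min to 11.81 at 290 min. PCL1 went from 7.26 to 11.63, under and then far above background. TOS6 (YNL300W), a cell surface protein gene, went from 9.22 at 30 min to 13.58 at 290 min. RNR1 went from 9.55 at 10 min to 12.75 at 270 min, and ACM1, which encodes an inhibitor of the anaphase-promoting complex, from 8.68 at 50 min to 10.69 at 290 min. Their F statistics over the 15 shared times were 548, 529, 513, 447 and 314, the highest of all genes, with adjusted p of 1.99e-16 or less. In all, 4602 of 5449 genes (84.5%) passed this test. After removal of a quadratic trend, the 2 cdc28-4 courses gave profiles that followed each other, with a median r between courses of 0.735 over all genes. The r was positive in 96.6% of them (genes are not independent replicates). The arrays at 30 min, soon after the shift, lay furthest from the times around them (SD over genes 0.411 and 0.363). A quadratic trend may not remove so sharp a change, so the shared response to the shift may enter this r. Agreement after 30 min alone was not computed. Methionine and sulfate genes had a median r of 0.964 and ribosome biogenesis genes of 0.962, both above all 10000 random lists matched on expression. SBF targets (0.837), MBF targets (0.646) and the CLB2 cluster (0.619) lay at percentiles 84.3, 18.8 and 13.9 of such lists. Without the 170 min samples, an omission chosen after seeing the data, the median r over all genes was 0.851.

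The comparison of both strains over time asked which transcripts changed in another way where Cdk1 activity was lacking. Histone genes, made in S phase, were higher at 90 than at 30 min in wild type (median 0.70) and lower in cdc28-4 (median -0.33). All 8 differed between strains, with HHO1 (YPL127C) at 1.19 against -1.24. Genes of the CLB2 cluster changed by a median of 1.15 in wild type and 0.048 in cdc28-4. Of these genes 17 of 19 differed: CLB1 by 2.01 (SE 0.20), the chitin synthase gene CHS2, needed for the division septum, by 1.75 (SE 0.14), and SWI5, the gene of a transcription factor of late mitosis, by 1.39 (SE 0.15). SBF targets changed by a median of 1.26 in wild type and 0.48 in cdc28-4, with 9 of 19 past the threshold. The difference for CLN2 did not pass (0.53 (SE 0.19), adjusted p = 0.0594), but did with the replicate block (adjusted p = 0.0280), and its adjusted p ran from 0.0280 to 0.313 over 7 alternatives. Methionine and sulfate genes, which bring in and reduce sulfate, were lower at 90 min in both, by a median of -0.49 in wild type and -1.85 in cdc28-4. MET3 (YJR010W), which encodes the first enzyme of the pathway, changed by -0.53 against -3.58.

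These values are the change from 30 to 90 min in wild type minus that in cdc28-4, a contrast chosen after the test over all 4 matched times had been seen. The 1 wild-type array per time was assumed to vary like the cdc28-4 pairs. A constant offset between the labelling kits cancels in it. Positive lists by camera, with the number of genes higher, were the CLB2 cluster (median 1.01, adjusted p = 7.58e-17), methionine and sulfate genes (17 of 18, median 1.45, adjusted p = 1.27e-19), MBF targets (23 of 31, median 0.70) and histones (median 1.01). So were spindle and Hcm1 genes (15 of 19, median 0.72), transcription factors (10 of 17, median 0.64) and cyclins (8 of 17 with 1 lower, median 0.51). With an estimated correlation these 7 lists still passed, with adjusted p from 0.0203 to 0.0238. SBF targets (median 0.54) and the heat shock chaperones, lower in 16 of 26 (median -0.45), passed with the preset correlation and were lost with adjusted p = 0.0565 for each with an estimated correlation. So were the phosphate genes (6 of 14 higher, median 0.36, adjusted p = 0.229 with an estimated correlation). The same held for the cell wall genes (median 0.57, adjusted p = 0.292), the hexose transporters (median -0.44, adjusted p = 0.0713) and the a-specific genes (median -0.45, adjusted p = 0.158). Adjusted over the list alone, the counts higher were 26 for MBF, 17 for the Hcm1 list, 12 for SBF and for the transcription factors, 10 for the cyclins and 7 for phosphate, and 18 chaperones were lower. The ribosome biogenesis list held 0 genes past the threshold in this contrast by limma, over all genes and adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median -0.032, camera adjusted p = 0.356).

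In all, 1053 genes differed in their change from 30 to 90 min, 591 higher and 462 lower in wild type than in cdc28-4. This balance depended on the scaling: with each array centred on its median the median of all genes moved by -0.14 and the counts were 367 higher and 844 lower, and with quantile normalization they were 546 and 565. Among the largest differences was that of HPF1, a mannoprotein gene, at 3.85 (SE 0.81). SIP18, a stress gene, fell from 13.15 in cdc28-4 and 9.03 in wild type to levels under the background of 8.27, and the permease gene SEO1 was under it at 30 min in wild type (8.17), so the size of their differences is not given. On the other side stood HSP30 at -1.92 (SE 0.41), the cell wall genes NCA3 at -1.84 (SE 0.22) and PRY1 at -1.69 (SE 0.16). Over the 4 matched times (30, 90, 150 and 210 min) 1841 genes (33.8%) changed differently in the strains, but 987 did without 30 min and 1110 without 210 min. TOS6 had the highest F (189): it stood at 10.19, 12.91, 12.81 and 11.43 in wild type and at 9.22, 11.65, 12.28 and 13.04 in cdc28-4. Next came HHO1 (182), MF(ALPHA)1 (153), the bud-site gene AXL2 (145) and SIP18 (132). By list, all 8 histone genes passed. They were joined by 17 of 19 genes of the CLB2 cluster, 17 of 19 SBF targets and 26 of 31 MBF targets (27 adjusted over the list alone). So did 1 of 18 ribosomal protein genes and 2 of 15 iron genes (0 by limma adjusted over the list alone, 4 unadjusted).

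**Figure D3:**
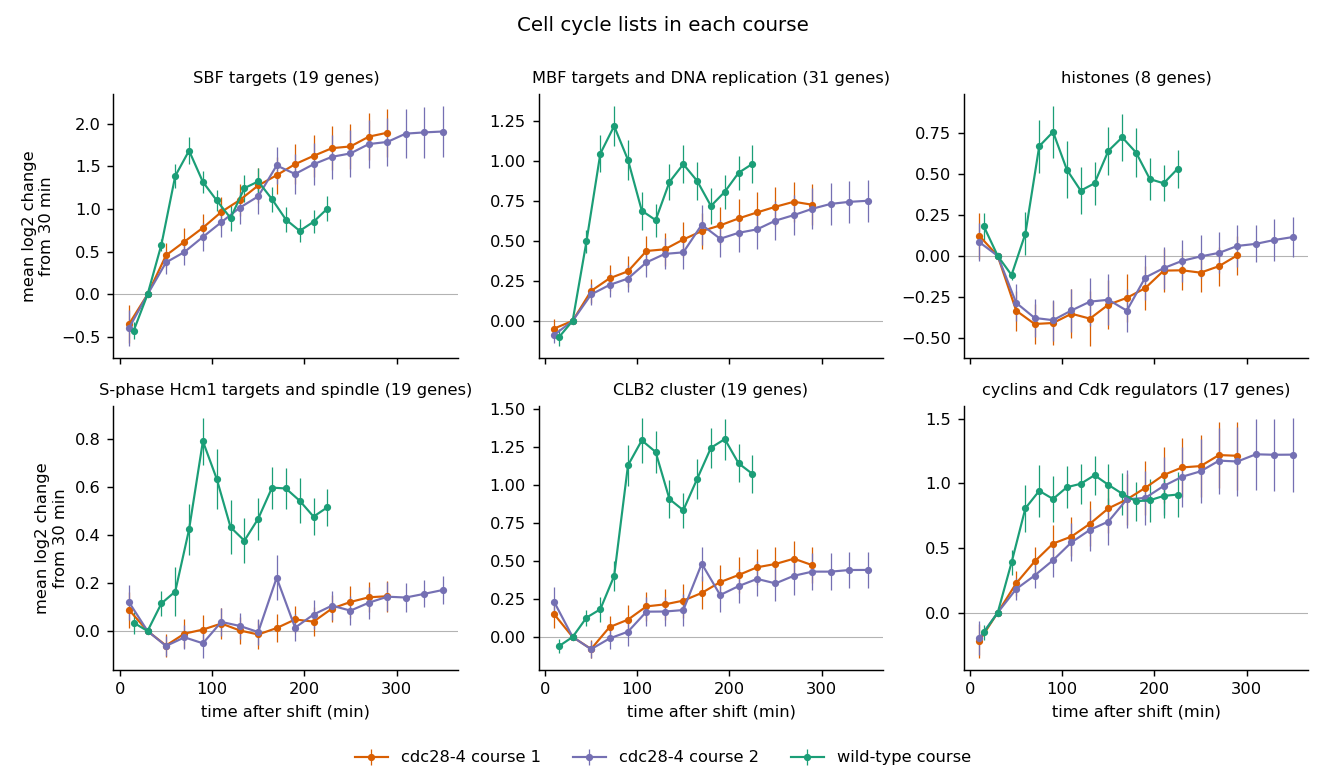
Mean log2 intensity change from 30 min (vertical axis) against minutes at 37 °C (horizontal axis) for SBF targets, MBF targets and DNA replication, histones, S-phase Hcm1 targets and spindle, CLB2 cluster and cyclins and Cdk regulators, 1 line per course, with bars for the standard error over the genes of a list. In wild type the SBF targets peak at 1.68 at 75 min and the CLB2 cluster at 1.30 at 195 min, and in cdc28-4 the SBF targets climb to 1.89 and 1.91 at the last times.

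Whether transcripts oscillate without Cdk1 was tested by fitting 1 wave of a shared period to each gene over a smooth trend. In the wild-type course the cell cycle lists followed a wave of 82 min, which took up 48.5% of the detrended variance of their 125 genes on average, and in cdc28-4 a wave of 82 min took up 8.83%. The highest share in cdc28-4 was 15.7%, at 160 min, the upper edge of the periods tried, so that no period inside the range stood out. SBF targets had a median amplitude of 0.369 in wild type and 0.0884 in cdc28-4, MBF targets 0.281 and 0.0513, and genes of the CLB2 cluster 0.242 and 0.0575. Each amplitude is that at the strain's own period.

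Few genes passed over all times. In wild type 3 of 5449 genes did (597 at an unadjusted p under 0.05): MSA1 (YOR066W), a G1 transcription gene, with an amplitude of 0.394 (SE 0.0525, adjusted p = 0.0453), YOR342C, a gene of unknown function, and NBA1, a bud-neck gene. All 3 had a larger amplitude than in cdc28-4, a direction that their choice by a wave in wild type and the other period in cdc28-4 largely fix, with adjusted p = 2.26e-05, 0.0285 and 0.00741. These calls depended on single arrays: limma passed 0 genes without any 1 of 12 of the 15 wild-type arrays (403 to 810 unadjusted), and 8 without that at 15 min. In cdc28-4, 40 genes passed at 160 min (1627 unadjusted), with the peptidase gene CPS1 first at an amplitude of 0.196 (SE 0.0282, adjusted p = 0.00457), then AXL2 at 0.168 and CLB5 at 0.113. They were followed by MF(ALPHA)1 at 0.484 and the ribonuclease gene RNH203 at 0.132. That count was 76 without the course 2 array at 170 min, an omission chosen after seeing the data, and 0 without course 1 (limma, 160 unadjusted) and 1 without course 2. At the wild-type period of 82 min limma passed 0 genes in cdc28-4 (210 unadjusted). Over all times 0 genes passed in both strains, so the order of peaks could not be compared. No gene list held more periodic genes than the rest by Fisher's exact test (lowest adjusted p = 0.0955, for SBF targets and transcription factors in cdc28-4). Adjusted over the list alone, wild type had 14 of 19 SBF targets, 27 of 31 MBF targets, 13 of 19 genes of the CLB2 cluster and all 8 histone genes past the threshold. In cdc28-4 the counts by limma were 2, 1, 0 and 0 in that order (4, 5, 2 and 0 at an unadjusted p under 0.05).

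The samples up to 30 min carry the stress response, and the count without them, an alternative set before the data were examined, was larger. In wild type 103 genes then passed at 78 min (share 59.6%, 999 unadjusted), 30 of them among the 125 genes of the cell cycle lists. In cdc28-4, at 160 min, 25 of those 125 genes passed. Without 1 array, an alternative chosen after seeing the data, the wild-type count of 103 became 4 to 316. SCW10, a cell wall gene, had an amplitude of 0.438 (SE 0.0413) in wild type and 0.0400 in cdc28-4, PCL1 0.513 and 0.0805, CLN2 0.543 and 0.0540, and SWI5 0.320 and 0.0249. SWI4, the gene of the DNA-binding part of SBF, had 0.206 in wild type and 0.168 in cdc28-4 and passed in both, with no difference shown (adjusted p = 0.501). HCM1, the gene of an S-phase transcription factor, had 0.362 and 0.181 (difference adjusted p = 0.0266). All these amplitudes are at 78 min in wild type and at 160 min, the edge of the range, in cdc28-4. Those of SWI4 and HCM1 therefore do not compare the same wave in both strains. In cdc28-4 both genes had their highest mean at 170 min, where the course 2 array stood apart from its neighbours. Of the 103 genes, which were chosen for a wave in wild type and fitted at another period in cdc28-4, 95 had a larger amplitude in wild type and 0 a smaller one by limma (96 of the 103 differed at an unadjusted p under 0.05). That choice largely fixes the direction, so the count does not measure how many genes lost their wave. By Fisher's exact test wild-type periodic genes were overrepresented among SBF targets (10 of 19, adjusted p = 6.9e-12), MBF targets (8 of 31, 7.85e-07) and Mcm1 genes (4 of 10, 0.000178). So were they among the cyclins and the transcription factors (each 4 of 17, 0.00109), histones (3 of 8, 0.00131), pheromone-induced genes (3 of 16, 0.0101) and cell wall genes (2 of 11, 0.0445). Adjusted over the list alone the counts were 19, 29, 8, 11, 11, 8, 3 and 6 in that order. The CLB2 cluster had 2 of 19 (17 adjusted over the list alone), which did not pass (0.113). The period of 78 min was chosen on these same arrays over the 125 genes of the cell cycle lists, which favours those lists in this test. Fisher's exact test, here and for cdc28-4 below, also treats genes of the same culture as independent.

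In cdc28-4 the same choice gave 1021 genes (18.7% of all), again at 160 min, the upper edge of the periods tried. At 78 min limma passed 0 genes (104 unadjusted). The courses end at 290 and 350 min, so after 30 min neither holds a wave of 160 min often enough to show that it repeats. A single rise and fall left by the trend can pass, so the 1021 genes are not shown to oscillate. The 1021 genes were overrepresented among Msn2 and Msn4 stress genes (17 of 23, adjusted p = 2.85e-07 by Fisher's exact test), ribosome biogenesis (19 of 32, 4.35e-06) and cell wall genes (6 of 11, 0.0479). They were not so among SBF targets (7 of 19, 0.158), of which 10 passed adjusted over the list alone. In both strains 24 genes passed, each strain at its own period. Of these, 8 belong to the cell cycle lists (AXL2, CSI2, HCM1, RME1, SRL1, SVS1, SWI4 and TOS6). Their peak phases had a circular correlation of -0.31 (permutation p = 0.474 over genes, which are not replicates). These phases belong to unlike waves, of 78 min in wild type and 160 min in cdc28-4, and to 8 genes only. The test therefore cannot decide whether the order of peaks was kept. The wild-type count rests on 1 culture and on single arrays of it. Leaving out 75 or 120 min gave 4 genes each and leaving out 45 min gave 316. Without course 1 of cdc28-4 its count was 0 by limma (582 unadjusted).

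**Figure D4:**
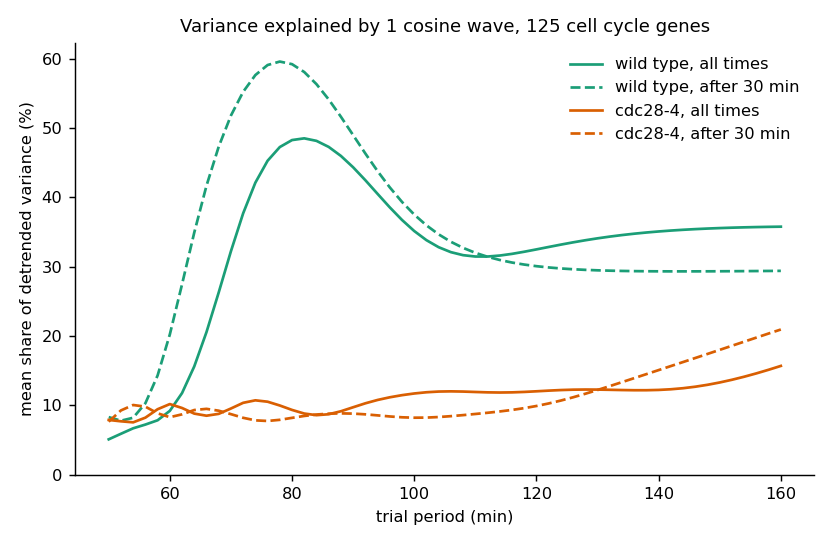
Mean share of the detrended variance (percent, vertical axis) that a wave of each trial period (minutes, horizontal axis) took up over the 125 genes of the cell cycle lists, for the wild-type course and both cdc28-4 courses, with all times and with times after 30 min. The wild-type lines peak at 82 min (48.5%) and 78 min (59.6%), and the cdc28-4 lines reach their highest shares, 15.7% and 20.95%, at the upper edge of 160 min. The strains differ in the number of arrays and courses, so the share expected by chance differs between their lines.

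**Figure D5:**
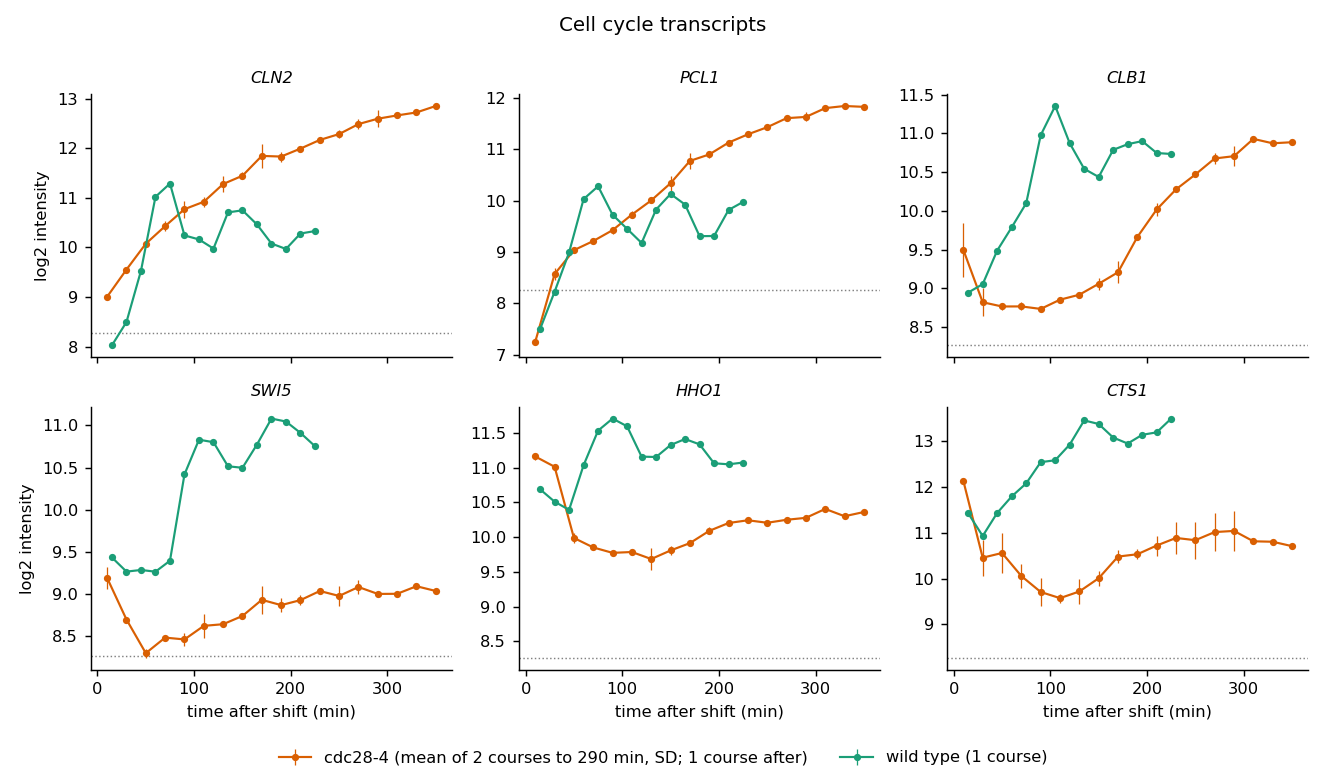
Log2 intensity (vertical axis) of CLN2, PCL1, CLB1, SWI5, HHO1 and CTS1 against minutes at 37 °C (horizontal axis). The cdc28-4 line is the mean of 2 courses with their standard deviation up to 290 min and 1 course after that, the wild-type line is 1 course, and the dotted line is the background of 8.27; PCL1 rises from 7.26 to 11.63 in cdc28-4, and in wild type it swings with a fitted amplitude of 0.513 after 30 min.

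The mean levels of both strains over the matched times were compared as 1 wild-type against 2 cdc28-4 course means, so that the spread comes from cdc28-4 alone and wild type was assumed to vary like it. Higher in wild type were all 8 histone genes (median 1.02), the daughter-cell gene DSE2 at 2.66 (SE 0.11) and the chitinase gene CTS1 at 2.29 (SE 0.11). So were 14 of 19 genes of the CLB2 cluster (median 0.61), 12 of 19 spindle and Hcm1 genes (median 0.54) and 22 of 31 MBF targets (median 0.48; 23 adjusted over the list alone). Lower in wild type were the G1 cyclin gene CLN3 at -1.23 (SE 0.075), 11 of 19 SBF targets (median -0.34), 19 of 23 Msn2 and Msn4 genes (median -0.53) and 17 of 26 chaperone genes (median -0.44). Lower too were 12 of 18 methionine and sulfate genes (median -0.39), 10 of 16 pheromone-induced genes (median -0.40), 5 of 6 a-specific genes (median -0.40), all 4 alpha-specific genes (median -0.92) and 7 of 11 cell wall genes (median -0.41).

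BAR1, which the wild-type label lists as bar1, was below background in wild type (7.46) and far above it in cdc28-4, a difference of at least 10.5-fold. SNL1 (YIL016W), a chaperone cofactor gene, and YIL014C-A, whose systematic names flank that of BAR1 (YIL015W), were at least 2.87-fold and 4.27-fold lower in wild type. YBL005W-A and YBL100W-A, genes of Ty1 transposons, were lower at -3.61 (SE 0.11) and -2.60 (SE 0.22). YDR034C-A, a short gene of unknown function, was higher in wild type, at 10.34 against a mean under background in cdc28-4 (7.56). The CDC28 transcript itself differed by -0.77 (SE 0.085) (wild type minus cdc28-4, adjusted p = 0.000406), and since cdc28-4 is a point allele this level does not check the strain. In all, 3560 genes (65.3%) differed in level, 1889 higher and 1671 lower in wild type. By the order in which the samples are listed, all cdc28-4 samples were labelled with 1 kit and all wild-type samples with another, so strain and kit cannot be told apart in these levels. The ratio of 3′ to 5′ control probe sets went with them too. It averaged 1.45 in wild type and 0.996 and 0.851 in the cdc28-4 courses on the log2 scale, and its part in these levels was not separated. Whether RNA quality or the kit set this ratio cannot be told apart. The lists above passed camera with the preset correlation (adjusted p from 0.000102 for the stress genes to 0.0201 for SBF targets). With camera at an estimated correlation all were lost (adjusted p = 0.674 for MBF and 0.635 for each of the others). That correlation comes from a fit of 3 course means, too few to estimate it. A list could hardly have passed, so this loss cannot decide whether the lists hold. For the cyclins, which were not called, the median of 0.067, the mean of -0.026 and the test differed in sign.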

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

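The tests of the mixing of cells and of the 170 min array, the centring on fission yeast probe sets and the contrast from 30 to 90 min were chosen after the results were seen, and the other tests and comparisons in this part were set before the data were examined. These results were picked out because the change in wild type and that in cdc28-4 differed by a test of the difference itself. Over the 4 matched times 1841 genes did, led by TOS6, a cell surface protein gene (F 189), the linker histone gene HHO1 (F 182), the alpha-factor gene MF(ALPHA)1 (F 153), the bud-site gene AXL2 (F 145) and the stress gene SIP18 (F 132), and 987 did without 30 min and 1110 without 210 min. From 30 to 90 min 1053 genes did. The median differences, wild type minus cdc28-4, were 0.51 for cyclins and Cdk regulators, 0.64 for cell cycle transcription factors, 0.70 for MBF targets, 1.01 for histones, and 0.72 for spindle and Hcm1 genes. They were 1.01 for the CLB2 cluster and 1.45 for methionine and sulfate genes. The fitted amplitude of 3 genes (MSA1, YOR342C and NBA1) was larger in wild type, which their choice by a wave in wild type largely fixes, and the SD over time of NBA1 was 0.166 in wild type and 0.181 in cdc28-4. Kit, the 3′ to 5′ control ratio and strain change together here. An effect of the kit or of RNA quality that varies with the RNA of each time point was therefore not separated from the strain. No combination of strain and time held enough arrays for a test of single samples within it.

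Alpha-specific transcripts rose late in cdc28-4, in cells labelled MATa: MF(ALPHA)1, SAG1 and STE3 were higher at 270 and 290 min than at 90 and 110 min. Alpha cells mixed in would keep these transcripts in 1 ratio if the levels in each such cell stayed constant. The rise over the 30 min level at 290 min, relative to that at 190 min, was 0.41 for MF(ALPHA)1 (SE 0.0020 over 2 courses). It was 0.774 for STE3 (SE 0.114) and 1.05 for SAG1 (SE 0.0900). The last pair lie 3.18 and 7.11 SE from MF(ALPHA)1, past the limit set for a difference. Each SE rests on 2 courses only, and alpha cells may change these transcripts separately over time. The ratios therefore cannot decide on mixed cells. A loss of silencing at the alpha cassette may also raise alpha genes, and would lower the haploid-specific genes together, but their median change was -0.039 (SE 0.22), with HO at 0.75, RME1 at 0.47 and FUS3 at -0.82, members that went apart, so this stays open. A response of the cells to the lack of Cdk1 activity stays open too: the change of MF(ALPHA)1 differed between the strains, but wild type has 1 course and its own kit.

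The course 2 array of cdc28-4 at 170 min stood apart from the arrays before and after it, with an SD over genes of 0.318, while 28 other arrays lay between 0.036 and 0.411, the higher ones both at 30 min (0.411 and 0.363). Its 18S rRNA probe set read 9.26, and the other 32 cdc28-4 arrays read 11.4 to 13.7, and its bacterial controls read 7.92 against 8.32 to 9.14. These probe sets carry no cell cycle signal, so a difference of this 1 array in RNA, labelling or hybridisation is a candidate explanation. A sample of another time of course 2 put in its place would lie as near to course 1 as the rest do, but its smallest distance to a course 1 array (root mean square over genes) was 0.315, at 170 min, against 0.121 to 0.185 for the other 17 course 2 arrays (SD 0.0154), which argues against such a swap as the only source. No biological explanation was tested for this array.

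SBF targets, among them CLN2 and PCL1, rose late in cdc28-4 with a median of 0.98. Scaling between arrays could produce a common rise, but the lowest median under 3 other scalings was 0.94. This argues against the choice among these scalings as its source. They moved the median of all genes by only -0.041 (median centring), -0.0027 (quantile normalization) and 0.040 (fission yeast probe sets). These scalings could thus hardly have taken the rise away, and no other scaling was tested. Among the 35 splits of the 8 arrays of this contrast into 4 and 4, only the real one (1 split) gave as many genes. It gave 3385 in a fit of those arrays, against 0 in the highest other split, a share of splits under the 0.05 set beforehand. These splits ignore the course, and every other split mixes early with late arrays, which widens its spread. They therefore cannot exclude chance. The 18 splits with 2 arrays of each course on each side are too few for a share under 0.05, and the highest other among them was 0. A change in RNA quality was not tested and stays open, since the 3′ to 5′ control ratio rose in the same contrast, and so does a biological cause, such as transcription that goes on without Cdk1 activity or the age and size of the cells, since no wild-type array is later than 225 min.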

How the results depend on the processing

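The scalings and omissions of the counts after 30 min, all settings of the change from 30 to 90 min, the wild-type period in cdc28-4, centring on fission yeast probe sets, and omission of 170 min samples and of courses in the interaction were chosen after seeing the data. All other alternatives were set before the data were examined, and the cause of each change was not tested. Counts stayed within 1.5 times for the time effect (3537 to 5054), 10 against 90 min (3369 to 4102), the late contrast (2352 to 3502), the change from 30 to 90 min (739 to 1571) and the level (3413 to 4274). With the replicate block they were 5054, 4102, 3502, 2740 for the interaction and 1571, and of 301 named genes 287 were the same and 14 gained a call. The interaction (1841) gave 987 without 30 min and 1110 without 210 min, and 987 to 2486 over omissions. Periodic genes in cdc28-4 (40) numbered 9 with median centring, 0 with a linear trend (limma, 1569 unadjusted) or no trend (1538 unadjusted), and 1021 after 30 min. They numbered 3 and 793 with a period 10 min shorter and longer, 2 with 2 harmonics, 2455 up to 230 min, 0 at the wild-type period (210 unadjusted) and 4 with a period per gene. Omissions gave 0 to 76, with 0 without course 1 (160 unadjusted), 1 without course 2 and 76 without the 170 min array of course 2. Periodic genes in wild type (3) numbered 9 with median centring, 1 with quantile normalization, 443 with a linear trend, whose period was 160 min, the edge of the range, in place of 82 min, 0 with no trend (limma, 209 unadjusted), and 103 after 30 min. They numbered 0 and 7 with a period 10 min shorter (408 unadjusted) and longer, 0 with 2 harmonics (259 unadjusted) and 297 with a period per gene. Omissions gave 0 to 8, with 8 without 15 min, 3 without 150 min, 1 without 210 min and 0 without any 1 of the other 12 arrays (403 to 810 unadjusted). Amplitude differences (3) numbered 8 with median centring, 1 with quantile normalization, 218 of 443 with a linear trend (also at 160 min) and 95 after 30 min. There were 1 to 2 without a course (1 without course 2), no value with no trend, and by SD over time 2 of 3 were larger in wild type. After 30 min, cdc28-4 (1021) gave 630 with median centring, 0 at the wild-type period (limma, 104 unadjusted), and 0 without course 1 (582 unadjusted) to 1381 without course 2. Wild type (103) gave 241 with median centring and, over omissions, 4 (75 or 120 min) to 316 (45 min), with 16 without 135 min, 29 without 90, 35 without 150, 43 without 180, 53 without 60, 55 without 195 and 57 without 225 min. The amplitude count (95) gave 214 with median centring and 83 to 93 without a course. Of 69 list tests (early, late and level contrasts, without that from 30 to 90 min) camera called 36, and 2 with an estimated correlation. Fry called 65 in either direction and 41 in 1 direction. In the level contrast the estimated correlation rests on 3 course means, with which a list could hardly pass. The agreement of courses (0.735) was 0.873 with no trend removed, 0.223 with either shift of 20 min and 0.851 without 170 min. Of 4448 values of named genes, 4266 were the same, 89 lost and 92 gained a call, and 1 reversed: the level of YOX1, 0.018 without 210 min, not past the threshold, against -0.37. Of 207 list medians 201 were the same, 2 lost and 4 gained a call. The cause was not tested. Signal limits the genes under background, since 90.8% to 96.6% of an array's genes lay above it.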

Other observations

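The values in this part belong to no comparison, and all were looked at after the data were seen. The alpha-specific genes of cdc28-4 were highest at 210 min, at 1.63 in course 1 and 1.51 in course 2 above their 30 min mean, and in wild type at 225 min, at 0.21. By course, the 18S rRNA probe set averaged 12.9 and 11.7 in the cdc28-4 courses and 13.7 in wild type on the log2 scale. The bacterial controls averaged 8.75, 8.60 and 7.82. The SD over genes of course 2 minus course 1 of cdc28-4 was 0.315 at 170 min, with a median of 0.158 and a lowest value of 0.121 over the shared times.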
